A study of Homo sapiens with 12 samples.

How the data were processed

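Total RNA was sequenced from 4 human ectodermal lineages and from undifferentiated cells of H9, an established human embryonic stem cell line (hESC). Per the labels, the lineages were obtained from pluripotent cells with small molecules and growth factors and collected on day 12, cells were sorted by FACS for a reporter signal, RNA was extracted with Trizol and a column kit, and libraries were made for Illumina sequencing. The groups were neuroectoderm (NE, PAX6 reporter, n = 3), neural crest (NC, SOX10 reporter, n = 3), cranial placode (CP, SIX1 reporter, n = 2), non-neural ectoderm (NNE, n = 3) and hESC (n = 1). The same sorting note stands with every library, but the labels name no reporter for NNE, so whether NNE was sorted is open, and it may be an unsorted, mixed culture. Nothing in the labels says whether replicates were separate cultures, so every p-value given here measures only the spread between samples.

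The first deposited table holds raw read counts per gene symbol, in 50995 lines, for all 12 libraries. The submitters' notes name TopHat 1.2, HTSeq, DESeq and the genome build hg19 without settings; the annotation version, the strand setting and the treatment of reads with several matches are not given in the sources used here. The second deposited table, by the authors, gives for each lineage and for hESC a signal, the mean normalized count per group, which equals the deposited counts divided by median-of-ratios size factors over the 12 libraries for all genes tested within a relative tolerance of 1.00e-06. In the same table the authors give a ratio, the fold of the lineage mean over the hESC mean, and the p-value and adjusted p-value of their comparison. Its log2 columns hold error marks in place of numbers and were not used. The counts were compared here from the first table, and the authors' own calls are quoted from the second under their name. The reference annotation at hand is of a later build than hg19, so no coordinates are printed; 25886 symbols matched its gene table. Among the symbols of the counts, 25 had been turned into dates by a spreadsheet and stayed unnamed, 7573 genes were at 0 in every library, and 383 lines for XIST and genes of the Y chromosome were left out of every step.

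Libraries held 32.3 to 55.2 M counts on 32895 to 35744 genes. A count of 3, the upper limit that a count of 0 allows, corresponds to 0.0504 to 0.0818 counts per M (CPM) in single libraries, on the scaled totals used for the levels. Such floors cover counting error only, since the reads carry no molecular identifiers. Levels are CPM with TMM scaling, given as mean ± SD over the libraries of a group. A gene at 0 in all libraries of a group is given as a lower bound on its fold, from 3 counts over the group, and a gene with few counts by its CPM, because its fitted change depends on the prior count.

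Counts were fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM scaling, filterByExpr by group, quasi-likelihood fit and test, and Benjamini-Hochberg adjustment, with a gene called at an adjusted p under 0.05. One fit of the 11 lineage libraries (27741 genes tested) served the contrasts among lineages, because CP has only 2 libraries, and a fit of all 12 libraries (29958 genes tested) served the contrasts with hESC. The common biological coefficient of variation of the first fit was 0.316. The lone hESC library is assumed to vary like the lineage libraries, so differences from it have no replicate check of their own. Each lineage was compared with the equal-weight mean of the other 3 on the log scale, and each pair of lineages was compared directly. On the log scale a gene near 0 in 1 lineage pulls that mean down, so a gene called higher in a lineage need not be highest there. A gene was counted as specific to a lineage when it was called higher against each of the other 3 with a log2 fold change of at least 1. The cells of 3 lineages were chosen by reporters of PAX6, SOX10 and SIX1, so the levels of these genes check the sort and are no finding.

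The comparisons, the 20 gene lists of 13 to 18 members (313 genes, all present in the table) and the rule for named genes were fixed before the data were examined. The lists were pluripotency, anterior neuroectoderm, neural crest, cranial placode, early non-neural ectoderm, epidermal keratinocyte, trophoblast and amnion, mesoderm and endoderm, mesenchyme and extracellular matrix, epithelial junction, neuronal differentiation, melanocyte and Schwann, BMP targets, WNT targets, FGF targets, Notch pathway, HOX 1 to 5, cell cycle, dissociation stress and mitochondrially encoded. Some genes stand in more than 1 list, among them CDH1, GRHL2, TBX3, HES5 and CCND1. Each list was described by its called members, adjusted over all genes tested and over the list alone, and tested with camera at a preset correlation of 0.01, adjusted over the 80 tests of 20 lists and 4 contrasts. Every camera call was lost with an estimated correlation, where the lowest adjusted p was 0.249. For pluripotency against hESC, the list median was set against 10000 random lists of the same size matched on mean expression.

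Named genes were, for each lineage against the others, the 10 with the largest log2 fold change up and the 5 down among those called, with at least 5 CPM on the higher side and every library of the lineage above or below every library of the other lineages. The reporter genes, up to 4 members of each list with the smallest adjusted p, and for each pair and each contrast with hESC the 3 largest up and 3 down under the same conditions were added. Where a gene family filled more than 3 places, further members were counted and not named, and ribosomal and small RNA species were never named. Other genes are named where a list count was small or a feature stood out, and are marked as chosen after their values were seen.

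The procedure was run on simulated counts with the mean of each gene over all libraries, the fitted spread and known increases in 1 lineage, and is thus tested on simulated data. Against the other lineages it recovered 35.9% of 2-fold changes for NE, 37.5% for NC, 28.6% for CP and 37.5% for NNE. It recovered 93.7%, 93.8%, 95.3% and 95.5% of 4-fold changes in the same order, and 100% of 8-fold changes for each. Unchanged genes were called in 0.0374%, 0.0227%, 0.0188% and 0.0300% of cases. Against the single hESC library it recovered 0%, 1.54%, 0% and 0% of 2-fold, 22.7%, 27.3%, 36.9% and 16.4% of 4-fold, and 74.2%, 62.1%, 66.7% and 66.7% of 8-fold changes. The simulated list with a true change was called in each lineage and 0 of 19 random lists were. Simulated genes varied independently of each other, so this does not measure false calls among lists of correlated genes. Few genes were changed, all upward, and the spread followed the trend with expression, not the spread of each gene. The real comparisons with the other lineages called 12.1 to 47.3% of genes, in both directions. The rates of recovery and of false calls therefore need not hold for the real data. Of genes changed at least 4-fold, 72.9%, 71.7%, 71.4% and 72.8% were counted as specific, and 0 unchanged genes were.

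Alternatives tried were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 3 libraries, the hESC library in the lineage fit, a fit of only the 2 lineages compared, a block on the replicate number, an adjusted p under 0.01, an added 2-fold minimum, each library left out in turn, and fry in place of camera. For the structure of the samples a prior count of 0.5 in place of 2 and the 500 most variable genes were tried. Leaving out NC library 2 and NNE library 2 together, leaving PAX6, SOX10 and SIX1 out of the gene lists, and removing structural and small RNA genes, were chosen after seeing the data. Upper-quartile scaling moved the median log2 fold change of all genes from -0.02 to 0.11 for CP against the others, from -0.07 to -0.19 for NNE against the others, from 0.05 to 0.24 for CP against NNE, from 0.03 to -0.08 for NC against CP, from 0.01 to -0.15 for NNE against hESC and from 0.08 to -0.03 for NC against hESC. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.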

Results

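The 12 libraries comprised 3 of neuroectoderm (NE), 3 of neural crest (NC), 2 of cranial placode (CP) and 3 of non-neural ectoderm (NNE), all at day 12 of differentiation, and 1 of undifferentiated H9 cells (hESC). The series sets the 4 major human ectodermal lineages side by side, and each comparison asks which genes set one of them apart. The labels name a different reporter for NE, NC and CP and none for NNE. A difference of lineage thus cannot be told apart from one of the reporter cells used. Total counts lay between 32.3 M and 55.2 M per library. The most abundant gene took 11 to 20.7% of counts, structural and small RNAs 16.7 to 27.4%, and mitochondrial messenger RNAs 0.451 to 0.926%. Spearman correlations of log2 CPM across genes were 0.947 to 0.986 within lineages and 0.850 to 0.955 between them, and genes are not independent replicates. The ranges overlapped, since NC library 2 correlated more with CP library 1 (0.955) than with NC library 3 (0.947). The difference of the means, 0.0737, exceeded the SD within lineages of 0.0112. CP and NC were the most similar pair (mean 0.939) and NE and NNE the least (mean 0.868). NE was the most similar to hESC (mean 0.917) and NNE the least (mean 0.870). No library had been deposited more than once, since counts of replicates differed by a chi-square per degree of freedom of 18.4 to 187.

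**Figure D1:**
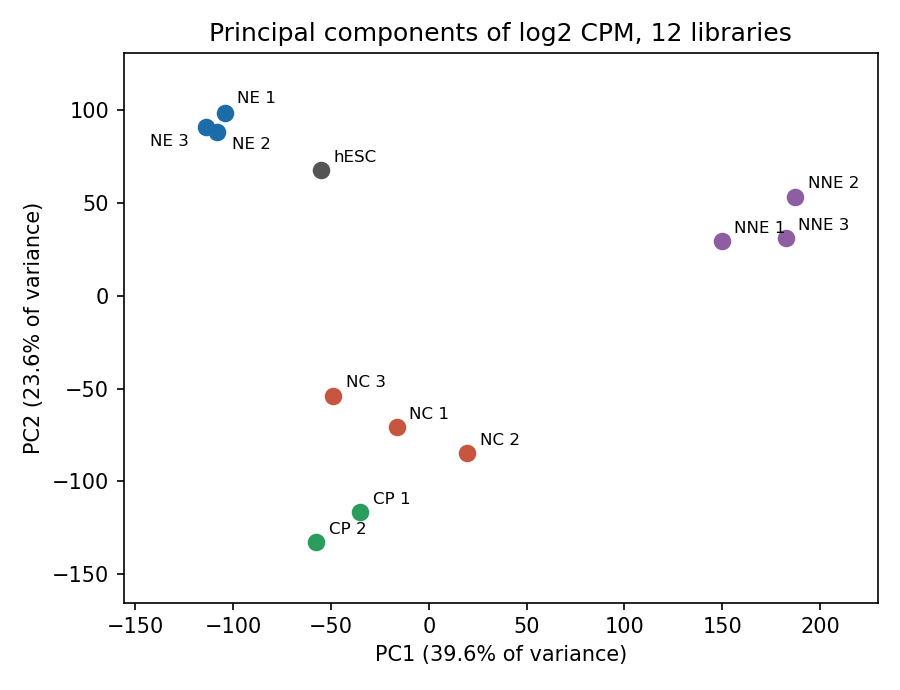
Principal components of log2 CPM over the 12 libraries, each point a library coloured by group. The horizontal axis (component 1) holds 39.6% and the vertical axis (component 2) 23.6% of the variance, and the library nearest to each lineage library is of the same lineage.

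The reporter genes were highest in the lineages sorted by them. PAX6, a factor of forebrain and eye, was at 242 ± 203 CPM in NE, 3.57 ± 3.33 in NC, 10.4 ± 4.52 in CP, 19.8 ± 24.6 in NNE and 0.772 in hESC. Its 3 NE libraries were at 132, 477 and 118 CPM. SOX10, a factor of migrating crest and glia, was at 214 ± 94.1 CPM in NC, 29.3 ± 19.7 in CP, 2.59 ± 1.46 in NE, 0.503 ± 0.252 in NNE and 1.51 in hESC. SIX1, a factor of the preplacodal region, was at 86.8 ± 13.8 CPM in CP, 45.9 ± 31.3 in NC, 5.45 ± 4.59 in NNE, 0.198 ± 0.0185 in NE and 0.487 in hESC. The log2 fold change over the other lineages was 4.74 (SE 0.74, adjusted p = 7.71e-04) for PAX6 in NE, 5.98 (SE 0.47, adjusted p = 2.48e-05) for SOX10 in NC and 4.56 (SE 0.50, adjusted p = 1.46e-04) for SIX1 in CP. SOX10 was also called in CP and SIX1 in NC, with log2 fold changes of 2.16 (SE 0.47, adjusted p = 0.00768) and 3.33 (SE 0.49, adjusted p = 0.00152), and the call of SOX10 in CP ended without CP replicate 1 (1.23).

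**Figure D2:**
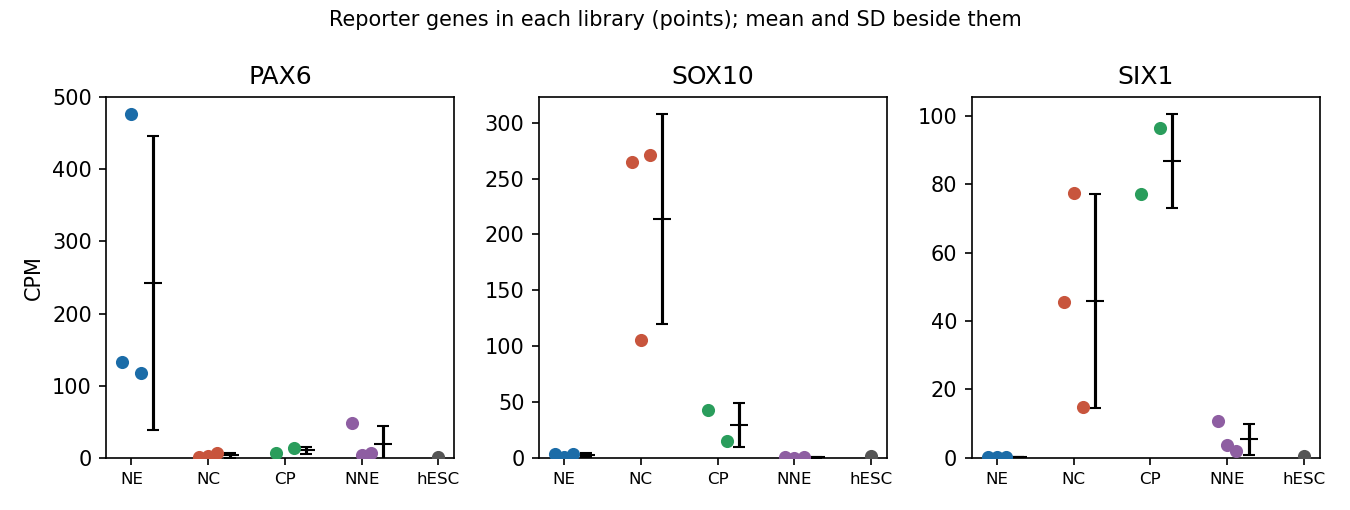
CPM of the reporter genes PAX6, SOX10 and SIX1 (vertical axis) in each group (horizontal axis), with points for libraries and group mean and SD beside them. Each gene is highest in the lineage sorted by it, at means of 242 CPM in NE, 214 CPM in NC and 86.8 CPM in CP.

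NE stood apart by transcription factors of the anterior neural plate. FEZF2, a forebrain patterning factor, was at 72.2 ± 18.6 CPM in NE, 0 in NC, 0.0555 ± 0.0785 in CP and 0.305 ± 0.297 in NNE (adjusted p = 5.75e-06). EMX2, which patterns the dorsal forebrain, was at 80.3 ± 41.9 CPM against 0.0329 to 0.414 in the other lineages (adjusted p = 1.53e-06). ARX, a factor of forebrain interneurons, was at 40.8 ± 37.3 against 0.0165 to 0.0836 (adjusted p = 1.66e-06). HES5, a Notch effector of neural progenitors, was at 213 ± 56.6 CPM in NE and 0.194 to 0.259 elsewhere (adjusted p = 2.65e-06). Undifferentiated cells held 0.0336, 0.0168, 0.0168 and 0.0839 CPM of these 4 genes. In the anterior neuroectoderm list 16 of 18 measured members were higher in NE and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 4.29e-12, adjusted p = 0.314 with an estimated correlation). Without PAX6, the gene of the sort, there were 15 of 17 higher and 0 lower (camera adjusted p = 1.30e-11). SIX6 and HESX1 were the members not called, named after their values were seen. LIX1, a list member, was called in NE with a log2 fold change of 3.78 (SE 0.18, adjusted p = 7.63e-07) although NNE held 186 ± 40.7 CPM beside 222 ± 46.9 in NE. NR2E1, a factor of neural stem cells, was at 29.3 ± 38.5 CPM in NE, and KLRF2 and CLEC2A, lectin-like receptor genes, at 66.1 ± 52.0 and 31.8 ± 20.1, against at most 0.425 in another lineage.

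Genes downstream of FGF signalling were higher in NE. The ETS factors ETV1, ETV4 and ETV5 had log2 fold changes of 3.49 (SE 0.22, adjusted p = 2.92e-06), 4.54 (SE 0.40, adjusted p = 2.18e-05) and 3.98 (SE 0.26, adjusted p = 3.38e-06). In the FGF targets list 12 of 14 members were higher and 1, PHLDA1, lower (12 and 1 adjusted over the list alone, camera adjusted p = 1.20e-06, adjusted p = 0.366 with an estimated correlation). In the Notch pathway list 7 of 14 were higher and HEY2 and DLL3 lower (8 and 2 adjusted over the list alone, camera adjusted p = 9.75e-04, adjusted p = 0.363 with an estimated correlation). DLL1, a Notch ligand, was at 221 ± 79.8 CPM in NE against 5.47 to 32.1 elsewhere. LFNG, which modifies Notch, was at 186 ± 81.9 against 2.77 to 21.7. In the cell cycle list 10 of 18 were higher and CCNE2 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.00339, adjusted p = 0.440 with an estimated correlation). TOP2A and BUB1, of mitotic cells, had log2 fold changes of 1.17 (SE 0.23, adjusted p = 0.00337) and 1.08 (SE 0.19, adjusted p = 0.00133). PHLDA1, HEY2, DLL3 and CCNE2 were named after their values were seen.

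Crest, surface and extraembryonic genes were lower in NE. TFAP2B, a crest and surface factor, was at 0.121 ± 0.121 CPM in NE against 151 to 289 in the other lineages (adjusted p = 1.11e-06). EDNRB, a receptor of crest cells, was at 0.0621 ± 0.0307 against 16.8 to 182. In the neural crest list 11 of 18 members were lower and 3 higher (3 and 11 adjusted over the list alone, camera adjusted p = 3.84e-06, adjusted p = 0.363 with an estimated correlation). The 3 were SOX8, NGFR and PLP1, named after their values were seen. The NC libraries held more PLP1 (542 to 2296 CPM) and NGFR (59.2 to 169) than the NE libraries (269 to 423 and 16.3 to 50.5). For SOX8 they overlapped (10.9 to 24.7 in NC and 3.28 to 12.2 in NE). In the early non-neural ectoderm list 14 of 18 were lower and 0 higher (0 and 15 adjusted over the list alone, camera adjusted p = 6.20e-08, adjusted p = 0.440 with an estimated correlation). TFAP2A, a surface and crest factor, was at 1.33 ± 0.351 CPM against 57.8 to 98.0. In the epithelial junction list 15 of 18 were lower and 0 higher (0 and 17 adjusted over the list alone, camera adjusted p = 5.30e-08, adjusted p = 0.470 with an estimated correlation). CDH1, the epithelial cadherin, was at 0.611 ± 0.391 CPM and its regulator GRHL2 at 0.605 ± 0.0770. In the trophoblast and amnion list 13 of 18 were lower and 0 higher (0 and 13 adjusted over the list alone, camera adjusted p = 4.68e-08, adjusted p = 0.440 with an estimated correlation). In that list VGLL1, a trophoblast cofactor, was at 0 in NE and at least 1121-fold lower than the mean of the others, and GABRP, an amnion marker, was at 0.101 ± 0.0599 CPM.

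Further lists were lower in NE. In the mesenchyme and extracellular matrix list 10 of 18 were lower and 1, COL6A1, higher (1 and 11 adjusted over the list alone, camera adjusted p = 8.33e-04, adjusted p = 0.470 with an estimated correlation). COL5A2 and COL1A2, fibrillar collagens, had log2 fold changes of -2.70 (SE 0.40, adjusted p = 5.32e-04) and -2.26 (SE 0.35, adjusted p = 7.22e-04). In the neuronal differentiation list 8 of 15 were lower and 1, NEUROG2, higher (1 and 9 adjusted over the list alone, camera adjusted p = 0.00283, adjusted p = 0.593 with an estimated correlation). ISL1, a sensory and motor neuron factor, was at 0.0918 ± 0.00936 CPM. In the BMP targets list 10 of 14 were lower and ID4 and SMAD6 higher (2 and 10 adjusted over the list alone, camera adjusted p = 5.05e-04, adjusted p = 0.363 with an estimated correlation). BAMBI and SMAD7, feedback inhibitors, had log2 fold changes of -2.04 (SE 0.28, adjusted p = 3.41e-04) and -1.53 (SE 0.21, adjusted p = 3.51e-04). In the HOX 1 to 5 list 3 of 7 measured members were lower and 0 higher (0 and 3 adjusted over the list alone, camera adjusted p = 0.00123, adjusted p = 0.440 with an estimated correlation). All 7 were called higher in NNE, which raises the mean of the others, and the filter partly set these 7, as given below. HOXB2, a hindbrain factor, was at 0.00810 ± 0.0140 CPM, and of the 3 only HOXB2 kept its call under every alternative. In the WNT targets list 7 of 14 were lower and LGR5, CCND1 and SP8 higher (3 and 9 adjusted over the list alone, camera adjusted p = 0.0410, adjusted p = 0.363 with an estimated correlation). This list call ended without NE replicate 1 (0.0703), NC replicate 2 (0.0703), CP replicate 2 (0.0512) or NNE replicate 2 (0.0718). In the epidermal keratinocyte list 6 of 15 were lower and 1, ITGA6, higher (1 and 7 adjusted over the list alone, camera adjusted p = 0.0415, adjusted p = 0.743 with an estimated correlation). Its call ended without NE replicate 2 (0.146), NE replicate 3 (0.0610), NC replicate 2 (0.0523), NNE replicate 1 (0.0540) or NNE replicate 2 (0.0718). COL6A1, NEUROG2, ID4, SMAD6 and LGR5 were named after their values were seen.

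In all, 8963 of 27741 genes were called in NE, 4721 higher and 4242 lower, and 1010 genes were specific to NE. The lower count was 2662 without NE replicate 1 and 2657 without NE replicate 3, and with a 2-fold minimum the balance turned to 3009 higher and 3068 lower. The specific count was 561 without CP replicate 1 and 446 without CP replicate 2, which leave a lone CP library. The other 6 lists were not called, at adjusted p of 0.132 to 0.903. They were pluripotency (2 higher and 2 lower of 11), cranial placode (5 and 4 of 16), mesoderm and endoderm (1 and 5 of 10), melanocyte and Schwann (3 and 7 of 12), dissociation stress (2 and 0 of 14) and mitochondrially encoded (1 and 0 of 13). The list median differed in sign from the test for the cranial placode and dissociation stress lists, and the list mean did for pluripotency.

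NC stood apart by genes of the neural crest. ITGA4, the alpha-4 integrin of migrating crest, was at 132 ± 47.9 CPM in NC, 49.5 ± 23.2 in CP, 1.89 ± 0.418 in NE, 0.488 ± 0.134 in NNE and 4.40 in hESC, a log2 fold change of 5.19 (SE 0.27, adjusted p = 1.47e-06). PAX3, which specifies the neural plate border, had one of 4.84 (SE 0.30, adjusted p = 4.34e-06), MPZ, a myelin gene of the Schwann lineage, one of 5.24 (SE 0.35, adjusted p = 8.22e-06), and TFAP2B one of 4.09 (SE 0.30, adjusted p = 1.75e-05). FOXD3, an early crest factor, was at 28.6 ± 15.3 CPM in NC, 9.63 ± 0.147 in CP, 0 in NNE and 5.39 in hESC. In the neural crest list 16 of 18 measured members were higher and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 6.06e-18, adjusted p = 0.249 with an estimated correlation). Without SOX10, the gene of the sort, there were 15 of 17 higher and 0 lower (camera adjusted p = 1.24e-16). SNAI2 and SOX9 were the members not called, named after their values were seen. In the melanocyte and Schwann list, not called, GFRA3, a receptor subunit, had a log2 fold change of 4.43 (SE 0.36, adjusted p = 3.08e-05) and SOX5 one of 1.72 (SE 0.23, adjusted p = 8.25e-04). Crest genes were unequal among the libraries, and those of the list had a median ratio of 0.429 in NC library 2 to the mean of libraries 1 and 3 (0.446 without SOX10).

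Some WNT target genes were higher in NC. SP5, a direct WNT target, had a log2 fold change of 5.60 (SE 0.42, adjusted p = 1.85e-05), RNF43, a feedback ligase, one of 2.86 (SE 0.26, adjusted p = 7.92e-05), and NKD1, a feedback inhibitor, one of 3.03 (SE 0.31, adjusted p = 1.67e-04). In the WNT targets list 6 of 14 were higher and 1, LGR5, lower (8 and 1 adjusted over the list alone, camera adjusted p = 4.34e-04, adjusted p = 0.249 with an estimated correlation), with LGR5 named after its values were seen. In the anterior neuroectoderm list 8 of 18 were lower and 0 higher (0 and 11 adjusted over the list alone, camera adjusted p = 1.47e-07, adjusted p = 0.363 with an estimated correlation), and LIX1 had a log2 fold change of -3.33 (SE 0.23, adjusted p = 1.21e-05). In the pluripotency list ZFP42 and LIN28A were higher, of 11 measured, and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.00358, adjusted p = 0.363 with an estimated correlation). ZFP42, a pluripotency factor, was at 51.8 ± 9.42 CPM in NC and 105 in hESC. The call of LIN28A ended without NC replicate 1 (1.17) or NC replicate 3 (1.09). In the Notch pathway list, not called, HEYL, a Notch effector, had a log2 fold change of 2.90 (SE 0.26, adjusted p = 5.96e-05) and DLL3 one of 1.51 (SE 0.19, adjusted p = 5.52e-04).

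The largest changes of NC were in genes nearly confined to it or absent from it. ZNF229, a zinc finger gene, was at 37.2 ± 3.74 CPM in NC and at most 0.0148 in other lineages (adjusted p = 3.38e-07). HIST1H4F, a histone gene, was at 88.9 ± 34.9 and at most 0.0262 (adjusted p = 2.16e-07), and ZC3HAV1L was at 16.6 ± 2.20 and at most 0.0353. ZNF667 was at 12.1 ± 2.38 and ZNF542 at 11.1 ± 0.144 CPM in NC, and hESC held 0.0336, 0.151, 0, 0 and 0.0504 CPM of these 5 genes. CHCHD2, a mitochondrial protein gene, was at 0.0900 ± 0.0399 CPM in NC against 35.7 to 59.7 in other lineages and 51.7 in hESC (adjusted p = 1.18e-07). ZNF248 was at 0.0224 ± 0.0223 CPM in NC against 14.3 to 29.8, and C17orf51 at 0.00740 ± 0.0128 against 6.20 to 15.1. MYH14, a non-muscle myosin gene, was at 0.00750 ± 0.0129 CPM in NC against 5.52 to 26.1.

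Epithelial, surface, extraembryonic and neuronal genes were called higher in NC against the log-scale mean of the others, although NNE or CP held more of most of them. Low levels pull that mean down, those of NE for many of these genes and those of NNE or CP for others. CDH1 was at 155 ± 177 CPM in NC and 636 ± 109 in NNE, and GABRP at 157 ± 155 and 1665 ± 208. The NC libraries 1, 2 and 3 held 92.6, 355 and 17.1 CPM of CDH1 and 148, 316 and 6.01 of GABRP. In the early non-neural ectoderm list TFAP2A, TFAP2C, DLX5, IRF6 and CDH1 were higher, of 18, and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 0.00952, adjusted p = 0.678 with an estimated correlation). In the trophoblast and amnion list 7 of 18 were higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.678 with an estimated correlation). In the epithelial junction list 7 of 18 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.0371, adjusted p = 0.760 with an estimated correlation). In the neuronal differentiation list 6 of 15 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.00969, adjusted p = 0.678 with an estimated correlation). NEUROG1, a sensory neurogenesis factor, was at 34.7 ± 5.09 CPM in NC and 85.4 ± 25.4 in CP. Without NC replicate 2 the early non-neural ectoderm (0.498), trophoblast and amnion (0.657) and neuronal (0.416) calls ended, and the epithelial junction list turned to lower without a call (0.932). The epithelial junction call also ended without NE replicate 2 (0.0910), NC replicate 1 (0.0525), CP replicate 2 (0.108), NNE replicate 1 (0.0540) or NNE replicate 3 (0.0657). The calls of CDH1 and IRF6 ended without NC replicate 2, at log2 fold changes of 1.15 and 1.72, and that of GABRP at 2.19. Those of CDH1 and GABRP also ended without CP replicate 2 (2.52 and 3.01), and that of GABRP without NC replicate 1 (3.26). DLX5 was at 0.626, 8.23 and 0.534 CPM in NC libraries 1, 2 and 3, and at 1.26 and 0.733 in the CP libraries. Its mean in NC thus rests on library 2.

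In all, 3350 genes were called in NC, 2342 higher and 1008 lower, and 232 were specific to NC. The count was 1421 without NC replicate 1 (1102 higher and 319 lower), 4431 without NC replicate 2 (2701 and 1730) and 2033 without NC replicate 3 (1547 and 486). It was 2176 without CP replicate 1 (1619 and 557) and 2027 without CP replicate 2 (1436 and 591), and DESeq2 called 1694 lower. The specific count was 100 without NC replicate 1, 456 without NC replicate 2, 148 without NC replicate 3, 68 without CP replicate 1 and 26 without CP replicate 2. Of the 20 lists 8 were called, 4 without NC replicate 2, and 47 of 100 regroupings of the libraries called as many. The other 12 lists were not called, at adjusted p of 0.161 to 0.945. They were cranial placode (3 higher and 0 lower of 16), epidermal keratinocyte (2 and 1 of 15), mesoderm and endoderm (2 and 0 of 10), mesenchyme and extracellular matrix (3 and 1 of 18), melanocyte and Schwann (3 and 1 of 12), BMP targets (0 and 3 of 14), FGF targets (0 and 3 of 14), Notch pathway (5 and 3 of 14), HOX 1 to 5, cell cycle, dissociation stress and mitochondrially encoded, the last 4 with 0 members called. The tests of the keratinocyte and HOX lists differed in sign from the median and mean of their members.

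**Figure D3:**
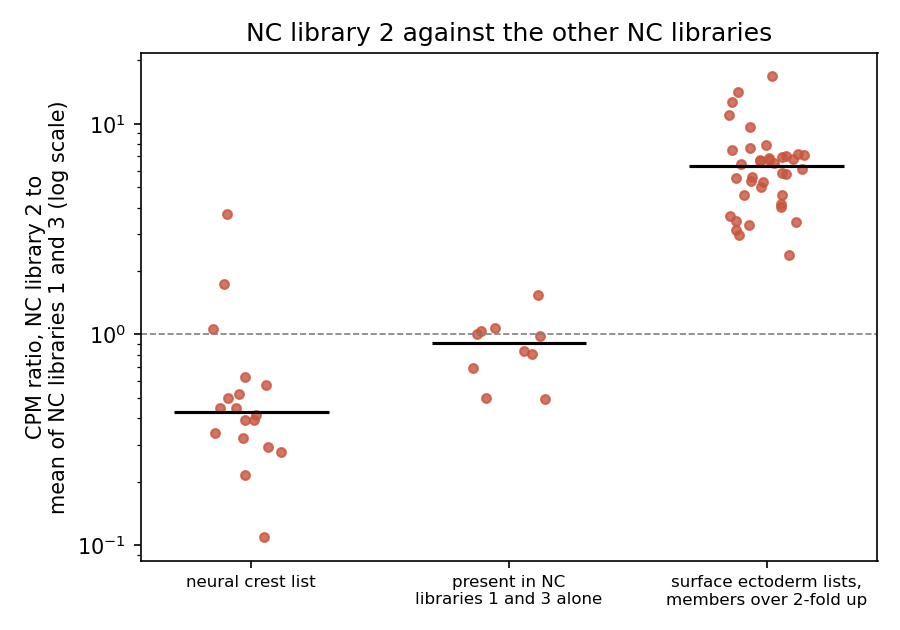
Ratio of CPM in NC library 2 to the mean of NC libraries 1 and 3 (vertical axis, log scale). Each point is a gene and each line a median. The sets are members of the neural crest list, genes present in NC alone and surface ectoderm members. The last were at 5 CPM or more and over 2-fold higher in library 2. The crest median is 0.429 and that of genes present in NC alone 0.912, with the dashed line at 1.

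CP stood apart by genes of neuronal differentiation. ISL1 was at 216 ± 44.5 CPM in CP, 94.5 ± 18.4 in NNE, 35.2 ± 26.7 in NC, 0.0918 ± 0.00936 in NE and 0.0168 in hESC, a log2 fold change of 4.99 (SE 0.44, adjusted p = 5.16e-05). POU4F1, a factor of cranial sensory neurons, had one of 5.29 (SE 0.51, adjusted p = 6.96e-05), NEUROG1 one of 4.71 (SE 0.49, adjusted p = 1.03e-04) and NEUROD1, a neuronal differentiation factor, one of 4.49 (SE 0.47, adjusted p = 1.19e-04). ELAVL4, an RNA-binding protein of neurons, was at 81.5 ± 14.4 CPM in CP against 0.323 to 1.54 elsewhere (adjusted p = 1.20e-04). In the neuronal differentiation list all 15 measured members were higher in CP (15 and 0 adjusted over the list alone, camera adjusted p = 1.11e-09, adjusted p = 0.363 with an estimated correlation). DLL3, a Notch ligand of nascent neurons, was at 62.7 ± 15.1 CPM in CP against 1.03 to 19.3 in other lineages, a log2 fold change of 3.79 (SE 0.19, adjusted p = 2.85e-06). LIPC, hepatic lipase, was at 13.5 ± 1.52 CPM in CP and at most 1.31 in another lineage. SOX21, a neural progenitor factor, was at 0.310 ± 0.0320 CPM in CP against 1.46 to 80.8, a log2 fold change of -5.23 (SE 0.36, adjusted p = 1.47e-05), and GCNT1, a glycosyltransferase gene, had one of -4.52 (SE 0.53, adjusted p = 2.45e-04).

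Of the placode genes, SIX4, EYA1, EYA2 and EYA4 were higher in CP, beside SIX1, by whose reporter CP was sorted. EYA2, a partner of SIX1, was at 177 ± 47.9 CPM in CP, 58.3 ± 29.1 in NC, 31.2 ± 8.21 in NNE and 2.22 ± 0.332 in NE, a log2 fold change of 3.48 (SE 0.26, adjusted p = 2.43e-05). EYA1 was higher in NNE (105 ± 18.7 CPM) than in CP (68.2 ± 3.74) by its mean, and its call in CP and that of SIX4 ended without CP replicate 1 (1.26 and 0.97) or CP replicate 2 (1.15 and 0.89). In the cranial placode list 5 of 16 measured members were higher and 0 lower, and the list was not called (5 and 1 adjusted over the list alone, camera adjusted p = 0.343, adjusted p = 0.760 with an estimated correlation). Without SIX1 there were 4 of 15 higher and 0 lower (camera adjusted p = 0.593).

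Crest genes were called in CP as well. PAX7, a factor of the neural plate border, was at 24.7 ± 7.60 CPM in CP and 4.76 ± 1.69 in NC, a log2 fold change of 4.77 (SE 0.30, adjusted p = 1.05e-05). TFAP2B, ITGA4 and PAX3 had ones of 3.88 (SE 0.31, adjusted p = 2.91e-05), 3.32 (SE 0.27, adjusted p = 3.21e-05) and 3.00 (SE 0.30, adjusted p = 7.97e-05). In the neural crest list 10 of 18 measured members were higher and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 8.34e-05, adjusted p = 0.433 with an estimated correlation). SOX10 in CP was at 13.7% of its NC mean, with CP libraries at 43.3 and 15.4 CPM. The mesenchyme and extracellular matrix list was not called in CP, with 3 members higher and 5 lower of 18. Of the 3, PRRX1 and POSTN were at 15.8 ± 17.6 and 11.2 ± 9.16 CPM in CP against at most 1.19 and 4.75 elsewhere (adjusted p = 1.31e-04 and 1.39e-04). The CP libraries 1 and 2 held 28.2 and 3.42 CPM of PRRX1 and 17.7 and 4.75 of POSTN. TBX3, a T-box factor, was at 131 ± 39.4 (adjusted p = 4.54e-04).

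Other lists were lower in CP. In the anterior neuroectoderm list 3 of 18 were lower and 0 higher (0 and 3 adjusted over the list alone, camera adjusted p = 2.58e-04, adjusted p = 0.440 with an estimated correlation), with LIX1 at -3.89 (SE 0.29, adjusted p = 2.43e-05). In the dissociation stress list 4 of 14 were lower and 0 higher (0 and 6 adjusted over the list alone, camera adjusted p = 8.44e-04, adjusted p = 0.565 with an estimated correlation). Immediate-early genes, chosen after their values were seen, were unequal between CP libraries 1 and 2 (FOS 74.9 and 5.55 CPM, EGR1 67.2 and 15.3). For FOS both were below every NE and NC library, but library 1 was above NNE libraries 1 and 3 (31.7 and 45.8). EGR1 and DUSP1 were higher in both CP libraries than in these NNE libraries, and JUN and ATF3 lower. NNE library 2, at 1524 CPM of FOS, also enters the mean of the others. In the HOX 1 to 5 list 0 of 7 members were called and the list was lower (0 and 0 adjusted over the list alone, camera adjusted p = 5.04e-04, adjusted p = 0.440 with an estimated correlation). All 7 were called higher in NNE, which raises the mean of the others, and the filter partly set these 7, as given below. This list call is thus no trait of CP by itself. In the epidermal keratinocyte list 4 of 15 were lower and 0 higher (0 and 4 adjusted over the list alone, camera adjusted p = 0.0154, adjusted p = 0.678 with an estimated correlation). ITGA6, an integrin of basal cells, had a log2 fold change of -1.92 (SE 0.29, adjusted p = 0.00109). In the FGF targets list 3 of 14 were lower and 0 higher (0 and 7 adjusted over the list alone, camera adjusted p = 0.0230, adjusted p = 0.662 with an estimated correlation). Without CP replicate 2 the keratinocyte (0.0665) and FGF targets (0.0922) calls ended. In the epithelial junction list 2 of 18 were lower and 0 higher (0 and 1 adjusted over the list alone, camera adjusted p = 0.0480, adjusted p = 0.760 with an estimated correlation). That call ended without NE replicate 1 (0.0592), NE replicate 3 (0.0685), NC replicate 1 (0.0525), NC replicate 2 (0.145), CP replicate 2 (0.329), NNE replicate 1 (0.0540) or NNE replicate 2 (0.0813). Of the called members of these lists LIX1 and ITGA6 kept their call under every alternative, and each of the others lost it under at least 1.

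In all, 6704 genes were called in CP, 4228 higher and 2476 lower, and 835 were specific to CP. The count was 3355 without CP replicate 1 (2444 higher and 911 lower) and 1513 without CP replicate 2 (1310 and 203), and the single CP library left is assumed to vary like the others. The specific count was 146 without NC replicate 1, 1343 without NC replicate 2, 483 without NC replicate 3, 214 without CP replicate 1 and 13 without CP replicate 2. Of the called genes 63.1% were higher, 73.8% with upper-quartile scaling and 86.6% without CP replicate 2. Of the 20 lists 8 were called, and 58 of 100 regroupings of the libraries called as many. The other 12 were cranial placode, given above, and 11 more that were not called, at adjusted p of 0.132 to 0.902. The 11 were pluripotency (1 higher and 0 lower of 11), early non-neural ectoderm (1 and 0 of 18), trophoblast and amnion (1 and 0 of 18), mesoderm and endoderm (3 and 1 of 10), mesenchyme and extracellular matrix (3 and 5 of 18), melanocyte and Schwann (3 and 2 of 12), BMP targets (3 and 5 of 14), WNT targets (3 and 1 of 14), Notch pathway (2 and 3 of 14), cell cycle (1 and 0 of 18) and mitochondrially encoded (0 called of 13). The list median differed in sign from the test for pluripotency and WNT targets, and the list mean did for melanocyte and Schwann.

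NNE stood apart by genes of surface epithelium. CDH1 was at 636 ± 109 CPM in NNE against 0.611 to 155 in other lineages. CDH3, the placental cadherin, was at 905 ± 199 against 14.5 to 74.0, log2 fold change 4.91 (SE 0.53, adjusted p = 4.00e-05). In the epithelial junction list all 18 members were higher (18 and 0 adjusted over the list alone, camera adjusted p = 6.20e-08, adjusted p = 0.470 with an estimated correlation). GRHL2 had a log2 fold change of 5.13 (SE 0.64, adjusted p = 9.91e-05) and SPINT2, a protease inhibitor, one of 3.36 (SE 0.34, adjusted p = 2.71e-05). In the early non-neural ectoderm list 14 of 18 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 4.82e-06, adjusted p = 0.470 with an estimated correlation). KRT19, a keratin of simple epithelia, was at 929.7 ± 277 CPM, TFAP2A at 98.0 ± 10.7, GATA2, a surface and trophoblast factor, at 46.5 ± 8.39 and MSX2, a BMP-induced factor, at 215 ± 45.4. In the epidermal keratinocyte list 9 of 15 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 5.48e-04, adjusted p = 0.565 with an estimated correlation). Levels of stratified keratins were low, with KRT14 at 0.398 ± 0.0963 and KRT15 at 2.28 ± 1.12 CPM, while FERMT1, an adhesion gene of keratinocytes, was at 103 ± 12.1 and LAMB3, a laminin chain of the basement membrane, at 24.3 ± 8.49.

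Trophoblast and amnion genes were higher in NNE. GABRP was at 1665 ± 208 CPM, VTCN1, a marker of amnion and trophoblast, at 801 ± 166, HAND1, a factor of extraembryonic tissue, at 399 ± 25.2 and HSD3B1, a placental steroid enzyme, at 10.8 ± 4.37, against 11.6, 0.319, 0.0168 and 0.0168 in hESC. The list had 14 of 18 members higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 1.80e-05, adjusted p = 0.470 with an estimated correlation). H19, an imprinted non-coding RNA, was at 3081 ± 319 CPM in NNE, 56.6 ± 40.1 in CP, 7.59 ± 4.10 in NE and 0.448 ± 0.255 in NC (adjusted p = 1.66e-06). LCP1, an actin-bundling protein gene, was at 1469 ± 243 CPM in NNE and at most 49.0 elsewhere, and HSPB7, a small heat shock protein gene, at 129 ± 24.1. In the HOX 1 to 5 list all 7 measured members were higher (7 and 0 adjusted over the list alone, camera adjusted p = 1.45e-05, adjusted p = 0.363 with an estimated correlation). HOXB2 was at 50.3 ± 12.3 CPM, HOXB3 at 9.23 ± 2.62 and HOXB1 at 6.83 ± 1.22. The list has 15 members, and a gene present in NNE alone passes the filter, as HOXB1 did (at most 0.0680 CPM in a library of another lineage). The count of 7 is thus partly set by the filter, and the HOX calls in NE and CP rest on the same 7 genes. In the BMP targets list 12 of 14 were higher and 1, ATOH8, lower (12 and 1 adjusted over the list alone, camera adjusted p = 1.20e-05, adjusted p = 0.314 with an estimated correlation). BAMBI, SMAD7 and NOG, a BMP antagonist, had log2 fold changes of 4.09 (SE 0.23, adjusted p = 1.93e-06), 3.12 (SE 0.18, adjusted p = 1.93e-06) and 3.00 (SE 0.36, adjusted p = 7.18e-05). ATOH8 was named after its values were seen.

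Matrix genes were higher in NNE, while neural and cell cycle genes were lower. SPARC, a matrix glycoprotein, was at 3013 ± 789 CPM (adjusted p = 1.98e-06), COL5A1 at 809.8 ± 188 and DCN, decorin, at 102 ± 17.8. In the mesenchyme and extracellular matrix list 14 of 18 were higher and COL6A1 and PRRX1 lower (14 and 2 adjusted over the list alone, camera adjusted p = 4.34e-04, adjusted p = 0.470 with an estimated correlation). In the neuronal differentiation list 13 of 15 were lower and ISL1 higher (1 and 13 adjusted over the list alone, camera adjusted p = 3.17e-04, adjusted p = 0.503 with an estimated correlation). GAP43, of growing axons, had a log2 fold change of -3.06 (SE 0.46, adjusted p = 3.05e-04). In the Notch pathway list 10 of 14 were lower and HEY1 and HEY2 higher (2 and 10 adjusted over the list alone, camera adjusted p = 0.00185, adjusted p = 0.366 with an estimated correlation). HEYL was at 0.555 ± 0.303 CPM and DLL1 at 5.47 ± 1.03. In the neural crest list 11 of 18 were lower, among them ITGA4, PAX3 and NGFR. TFAP2B, SNAI2, ETS1, ERBB3 and EDNRB were higher (5 and 11 adjusted over the list alone, camera adjusted p = 0.00463, adjusted p = 0.476 with an estimated correlation). Of these 5, only SNAI2 was higher in every NNE library than in every library of the other lineages. Low levels in NE pull the log-scale mean of the others down. TFAP2B was at 123 to 167 CPM in the NNE libraries, below NC (257 to 310) and CP (229 to 289). ERBB3 was at 96.8 to 109 in NNE and 183 to 339 in NC, and for ETS1 and EDNRB the NNE and NC libraries overlapped. ISL1 was likewise lower in NNE (74.3 to 110) than in CP (184 to 247). In the cell cycle list 11 of 18 were lower and 0 higher (0 and 12 adjusted over the list alone, camera adjusted p = 0.00602, adjusted p = 0.440 with an estimated correlation), with TOP2A at -1.48 (SE 0.27, adjusted p = 0.00107). PTPRZ1, a receptor phosphatase of neural progenitors, was at 0.976 ± 0.938 CPM in NNE against 114 to 315. PLP1, a myelin gene, was at 4.27 ± 3.04 against 329 to 1487. PRRX1, HEY1, HEY2, SNAI2 and ETS1 were named after their values were seen.

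The labels name no reporter for NNE, so its levels and counts may be those of an unsorted, mixed culture. In all, 13131 genes were called in NNE, 6792 higher and 6339 lower, and 2126 were specific to NNE, 1405 without CP replicate 2. With upper-quartile scaling 5964 were higher and 7432 lower, and with a 2-fold minimum 4321 and 4534, so the balance of directions depends on the processing. Of the 20 lists 11 were called, and 26 of 100 regroupings of the libraries called as many. The other 9 were not called, at adjusted p of 0.0501 to 0.947. They were pluripotency (1 higher and 6 lower of 11), anterior neuroectoderm (2 and 8 of 18), cranial placode (3 and 4 of 16), mesoderm and endoderm (2 and 3 of 10), melanocyte and Schwann (5 and 5 of 12), WNT targets (4 and 6 of 14), FGF targets (2 and 7 of 14), dissociation stress (5 and 0 of 14) and mitochondrially encoded (0 called of 13). NNE library 2 held 1524 CPM of FOS and 781 of ATF3, immediate-early genes, against 31.7 and 45.8, and 33.2 and 33.2, in libraries 1 and 3. The calls of JUN, IER3, ATF3 and ZFP36 in NNE ended without it, at log2 fold changes of 1.23, 0.20, 0.02 and 0.61.

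**Figure D4:**
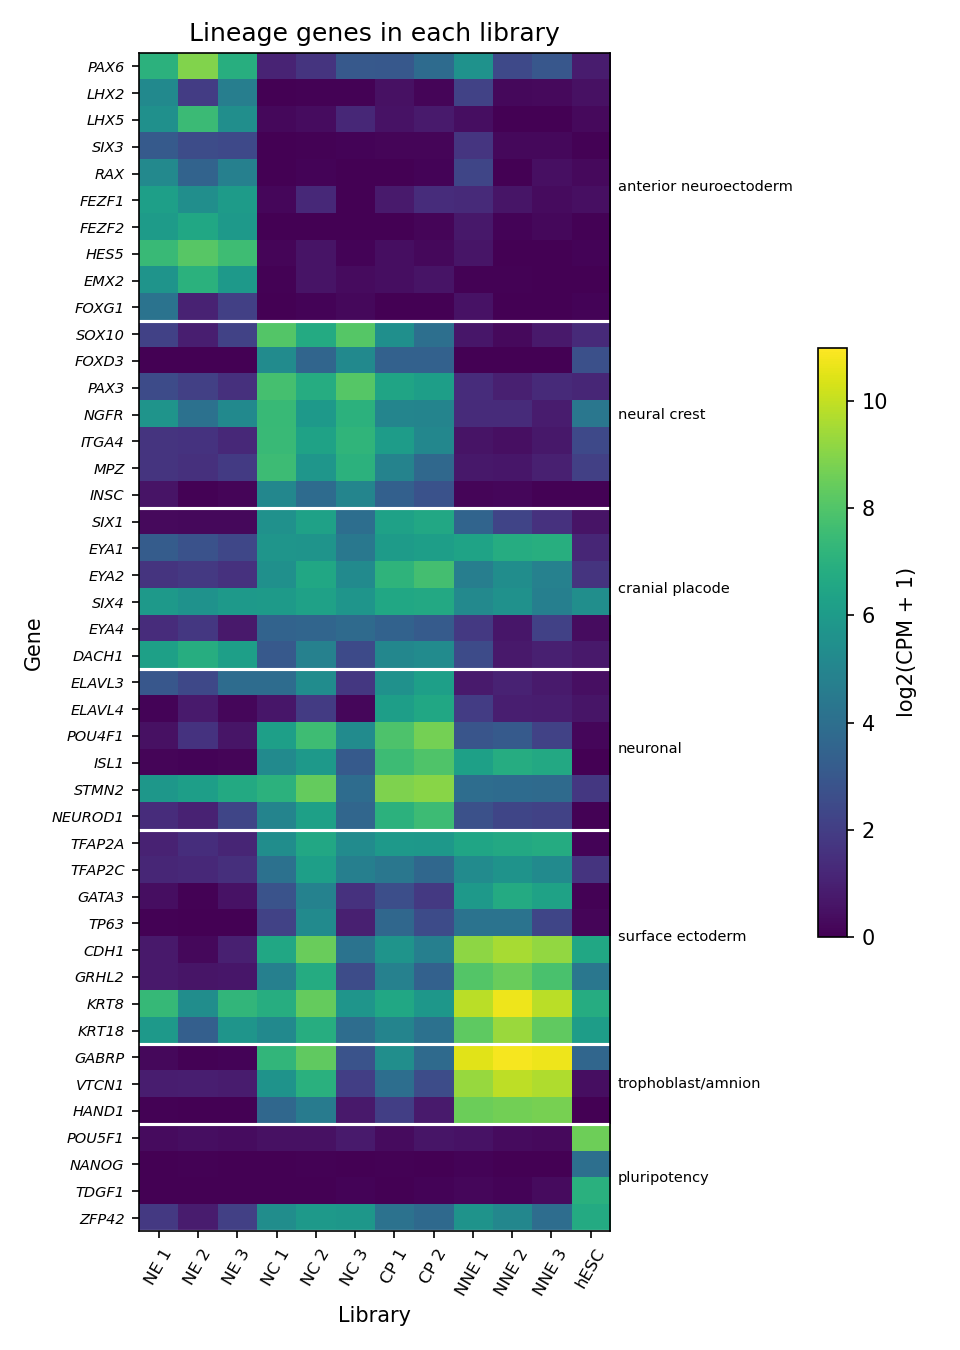
Heat map of log2(CPM + 1) for genes chosen from the lists (vertical axis, in bands by list) in the 12 libraries (horizontal axis, by group), with brighter colour for higher levels. The lineage means are highest in NE for FEZF2 (72.2 CPM), in NC for SOX10 (214 CPM), in CP for ISL1 (216 CPM, and 94.5 in NNE) and in NNE for CDH1 (636 CPM, and 155 in NC).

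Between pairs of lineages the extremes were of the same kinds. FEZF2 was at least 3219-fold higher in NE than in NC (adjusted p = 5.90e-05). LINC00379, a non-coding RNA at 0 in NE, was at least 736-fold lower in NE than in NC and at least 991-fold lower than in CP. VGLL1 and CGA, the shared alpha subunit of glycoprotein hormones, were at least 2567-fold and 2149.6-fold lower in NE than in NNE. Between NC and CP, ZNF229 was at least 1032-fold higher in NC, and C17orf51 and ZNF248 were lower in NC (adjusted p = 1.21e-05 and 1.49e-05). FOXD3, at 0 in NNE, was at least 1179-fold higher in NC and at least 397-fold higher in CP. HOXB1, at 0 in CP, was at least 189.6-fold lower there than in NNE, and H19 had a log2 fold change of -12.74 (SE 0.82, adjusted p = 6.46e-06) in NC against NNE.

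Called genes numbered 6417 between NE and NC (2937 higher in NE and 3480 lower), 7171 between NE and CP (3218 and 3953) and 11972 between NE and NNE (5935 and 6037). They numbered 2605 between NC and CP (1140 higher in NC and 1465 lower), 10262 between NC and NNE (5111 and 5151) and 11780 between CP and NNE (6099 higher in CP and 5681 lower). NC and CP differed by the fewest genes. Their count was 454 without NC replicate 1 (222 higher in NC and 232 lower), 4496 without NC replicate 2 (1904 and 2592) and 1510 without NC replicate 3 (779 and 731, a turned balance). It was 555 without CP replicate 1 (229 and 326) and 72 without CP replicate 2 (28 and 44). The count of NE and NC was 4191 without NE replicate 3 (2086 higher in NE and 2105 lower), with 2304 lower without NE replicate 1 and 1837 higher without NC replicate 1. That of NE and CP was 3689 (1416 and 2273) and 2444 (813 and 1631) without CP replicates 1 and 2, with 2586 lower without NE replicate 1. That of CP and NNE was 7815 (4301 and 3514) and 5604 (3224 and 2380) without CP replicates 1 and 2. The share of called genes that were higher was 44.9% between NE and CP, 33.3% without CP replicate 2, and 43.8% between NC and CP, 32.6% with upper-quartile scaling. That scaling also turned the balance between NE and NNE (6618 higher in NE and 5477 lower) and between NC and NNE (5717 higher in NC and 4704 lower). With libraries left out it turned between NE and NNE without NE replicate 1 (4991 and 4968) or NE replicate 3 (4873 and 4850), between NC and NNE without NC replicate 1 (3814 and 3583) and between CP and NNE without NC replicate 3 (5901 and 5902).

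Against undifferentiated cells, core pluripotency genes were lower in every lineage. POU5F1, a core pluripotency factor, was at 380.5 CPM in hESC and 0.294 to 0.515 in the lineages, and NANOG at 15.3 and 0.0151 to 0.0373. TDGF1, a Nodal co-receptor, was at 126 CPM in hESC and 0 in NE, at least 5541-fold lower there. LIN28B, an RNA-binding protein of early cells, was not called in any lineage, at 288 ± 82.7 CPM in NE and 139 in hESC. LIN28A was called in NNE alone of the 4 contrasts, at -1.99 (SE 0.44, adjusted p = 0.00781). Of 17 measured members, 12 were lower in NE, 11 in NC, 12 in CP and 13 in NNE, and 0 were higher in any, with 13, 13, 12 and 16 lower and 1, 0, 0 and 0 higher adjusted over the list alone. The median log2 fold change was -5.55, -3.02, -3.82 and -4.01, each below all 10000 random lists, whose 95% ranges were -0.41 to 0.58, -0.40 to 0.71, -0.48 to 0.73 and -0.57 to 0.76. With genes at 0 set to their bound and genes of 1 to 3 counts to their CPM ratio, the medians were -5.55, -3.02, -3.42 and -3.99. A gene present in the hESC library alone passes the filter of this fit, and such a member can only come out lower. In the fit of the lineage libraries 11 members were measured. The random lists were not chosen in that way, so the place of the medians among them is descriptive. With a filter of 1 CPM in 3 libraries, which a gene present in the hESC library alone cannot pass, fewer members were lower, as given below. GRIA2, a glutamate receptor gene at 0 in hESC, was at least 4352-fold higher in CP, and DMRT3, a neural factor, at least 459.6-fold higher in NE. SLN, sarcolipin, and GBP2, an interferon-induced gene, were at 0 in hESC and at least 2936-fold and 2929-fold higher in NNE.

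Called genes against hESC numbered 3373 in NE (1448 higher and 1925 lower), 4216 in NC (1960 and 2256), 4898 in CP (2353 and 2545) and 7828 in NNE (3707 and 4121). These rest on a single hESC library, and their balance of directions depends on the tool. DESeq2 called more genes higher than lower in NE (2350 and 2117), NC (2830 and 2437), CP (3058 and 2758) and NNE (4468 and 3893). Upper-quartile scaling gave more lower in NE (1300 and 2330), NC (1728 and 2863), CP (2355 and 2547) and NNE (3093 and 5029). The NE count was 2155 without NE replicate 3 (952 higher and 1203 lower), with 1283 lower without NE replicate 1, and the NC count was 2571 without NC replicate 1 (1225 and 1346). The CP count was 2323 (1154 and 1169) and 1432 (791 and 641) without CP replicates 1 and 2. In the authors' deposited table, at the same threshold, 1828 genes were called in NE (488 higher and 1340 lower), 2368 in NC (847 and 1521), 2673 in CP (1155 and 1518) and 3996 in NNE (1480 and 2516). In the authors' deposited table the fold of PAX6 in NE was 311 (adjusted p = 0.727), that of SOX10 in NC 139 (adjusted p = 0.0615) and that of SIX1 in CP 177 (adjusted p = 8.24e-04). In the fit used here the log2 fold changes of these genes over hESC were 8.29 (SE 2.10, adjusted p = 0.0283), 7.14 (SE 1.18, adjusted p = 0.00317) and 7.47 (SE 1.34, adjusted p = 0.00507), and the call of PAX6 ended with a block on replicate number.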

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

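Leaving out NC library 2 and NNE library 2 together and removing structural and small RNA genes were chosen after seeing the data. So was leaving PAX6, SOX10 and SIX1 out of the lists. All other alternatives were set before. Of 424 results on named genes, 338 kept their direction and call under every alternative that gave a value and 86 lost the call at least once, with 8092 alternative values the same, 290 without the call and 0 reversed. Of 41 called lists, 578 alternative values were the same, 77 lost the call and 1 was reversed, that of the epithelial junction list in NC without NC replicate 2 (adjusted p = 0.932). With 1 library left out in turn, the adjusted p of that list ranged from 1.16e-08 without NC replicate 3 to 0.932. DESeq2, RLE scaling, upper-quartile scaling, no filter, the hESC library in the fit and removal of structural and small RNA genes kept every total within 1.5 times, except that DESeq2 called 3929 genes between NC and CP (1902 higher in NC and 2027 lower). Single directions moved more with DESeq2, to 1694 lower in NC against the others and 2350 higher in NE against hESC. Over all alternatives the direction with more called genes turned in 22 of 310 values, in 10 of 14 comparisons, so in those comparisons which direction held more genes depends on the processing.

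At an adjusted p under 0.01, by construction, fewer genes were called: 5089 in NE, 1321 in NC and 3205 in CP against the other lineages. The pairs gave 3009 between NE and NC, 3351 between NE and CP, 7975 between NE and NNE, 254 between NC and CP, 5936 between NC and NNE and 6982 between CP and NNE. There were 1095, 1423, 1530 and 3606 in NE, NC, CP and NNE against hESC, and 532, 57 and 91 specific to NE, NC and CP. With an added 2-fold minimum NC had 2231, and the balance turned between NE and NNE (4614 higher in NE and 4507 lower) and between NC and NNE (3876 and 3623). With no filter it turned between NE and NNE (6098 and 6069) and between NC and NNE (5140 and 5002), and with 1 CPM in 3 libraries between CP and NNE (4374 and 4535) and in CP against hESC (1830 and 1815). A filter of 1 CPM in 3 libraries left 4369 in CP, 1506 between NC and CP, 133 specific to NC and 354 specific to CP. It left 5, 4, 4 and 5 lower pluripotency genes in NE, NC, CP and NNE. Fewer genes are tested with this filter. By construction, a gene over 1 CPM in the 1 hESC library alone, or in the 2 CP libraries alone, cannot pass it. A fit of only the 2 lineages gave 660 between NC and CP. Leaving out NC library 2 and NNE library 2 gave 5410 between NC and CP, 5269 and 7560 in NE and CP against hESC, and 579 and 1390 specific to NC and CP. Camera with an estimated correlation called 0 lists in NE, 0 in NC, 0 in CP and 0 in NNE, and fry called 5 in CP. Leaving PAX6, SOX10 and SIX1 out of the lists changed 0 of the 80 list calls. The difference between correlations within and between lineages was 0.676 over the 500 most variable genes, and a prior count of 0.5 cannot move it, since ranks stay. Where no construction is named, the cause was not tested.

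Same-number libraries of different lineages were not paired, since 0 of 15 pairs correlated above 0.1 after removal of lineage means (-0.112 to 0.0977) and 3 of 11 libraries correlated best with their own number. With a block on that number 1209 genes were called between NC and CP, 2034 in NE and 2673 in NC (1337 higher and 1336 lower) against hESC, and 154 and 435 were specific to NC and CP. The block uses up degrees of freedom, and counts do not show whether effects differ.

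With 1 library left out in turn, counts ranged from 6112 to 9358 in NE, 1421 to 4431 in NC, 1513 to 7985 in CP and 10665 to 13756 in NNE. Between pairs they ranged from 4191 to 6929 between NE and NC, 2444 to 8306 between NE and CP, 9723 to 12768 between NE and NNE, 72 to 4496 between NC and CP, 7397 to 10942 between NC and NNE and 5604 to 12699 between CP and NNE. Against hESC they ranged from 2155 to 4293 in NE, 2571 to 4863 in NC, 1432 to 6193 in CP and 6045 to 9043 in NNE. Specific genes ranged from 446 to 1037 for NE, 26 to 456 for NC, 13 to 1343 for CP and 1405 to 2470 for NNE, called lists from 13 to 14, 4 to 9, 6 to 9 and 11 to 12, and lower pluripotency genes from 12 to 13, 10 to 13, 9 to 13 and 12 to 16. Without a CP replicate 1 CP library is left, which is assumed to vary like the other groups; CP replicate 2 gave the lowest and NC replicate 2 the highest counts of most comparisons of CP. Levels under 0.0504 to 0.0818 CPM, by library, rest on under 3 counts and are not resolved at this depth.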

Other observations

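The tests of NC library 2, of crest genes in CP and of genes present in NC alone were chosen after the result was seen, while the regroupings of libraries were planned. The imprinted genes DLK1, MEG3, IGF2 and NNAT were chosen after their values were seen, and say nothing of imprinted genes as a group, for which no list was tested. DLK1 was at 1996, 56.2 and 1017 CPM in the NE libraries and MEG3, of the same imprinted locus, at 18.9, 0.789 and 8.92, with MEG3 at most 0.104 in the mean of another lineage. IGF2 was at 96.7 ± 51.9 CPM in NNE, 99.3 ± 121 in NC, 5.10 ± 2.56 in CP and 1.89 in NE. NNAT was at 358 ± 83.5 CPM in CP, 209 ± 44.9 in NE, 29.8 ± 7.95 in NNE, 1.10 ± 0.201 in NC and 23.4 in hESC.

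Single genes, again chosen after their values were seen, are given for NNE, with no test of a tissue behind them. KDR, a receptor for VEGF, was at 212 ± 134 CPM in NNE and 1.76 in CP, 3.80 in NC and 11 in NE, with 111 in hESC. PGR, the progesterone receptor, was at 89.0 ± 67.6 CPM in NNE and at most 0.938 in another lineage, and ALOX15, a lipoxygenase gene, at 53.4 ± 7.62 and at most 0.631. TNNT2, cardiac troponin T, was at 22.0 ± 9.52 CPM in NNE, TCF21, a mesodermal factor, at 9.13 ± 3.59, and SMYD1, a muscle gene, at 32.5 ± 11.9 (at most 0.329 in another lineage). GATA6 was at 6.58 ± 1.37, TBX20 at 2.00 ± 0.199, TBX5 at 1.53 ± 1.64, HAND2 at 0.867 ± 0.524, GATA4 at 0.186 ± 0.117 and CD34 at 0.142 ± 0.0525 in NNE, the last below its 0.544 in NE. The mesoderm and endoderm list was not called in NNE, with 2 of its 10 members higher and 3 lower, and whether NNE held cells of another tissue was not tested.

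Of the epithelial junction, early non-neural ectoderm and keratinocyte lists 49 genes were measured, 3 held by more than 1 list. Of the 49, 34 were over 1 CPM in both NC library 1 and NC library 3. In NC library 2, 38 were at 5 CPM or more and over 2-fold above both other NC libraries. KRT8 was at 334 CPM there against 114 and 52.6. Cells of the NNE cultures mixed in are argued against as the whole source, since 13 of the 38 lay above every NNE library. Cells of any other lineage's cultures are argued against too, since 11 genes silent in NC libraries 1 and 3 and present in all 8 other lineage libraries reached in NC library 2 a median of 0.520% (at most 5.95%) of their lowest level there. Epithelial cells of the same reporter cultures inside the sorted cells stay open as a part of it: crest list genes had a median ratio of 0.429 to the other NC libraries (15 of 18 under 0.7, and without SOX10, the gene of the sort, 0.446 and 14 of 17) while 10 genes present in NC alone had 0.912 (0.494 to 1.54). Epithelial cells alone would not be expected to bring all of it, since 9 of 15 neuronal list genes were raised there by the same limits (STMN2 332 CPM against 132 and 13.8), so other cells without crest genes, or a difference in the crest cells themselves, stay open and untested, and a strict reporter gate would remove such cells.

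Crest genes in CP might come from cells of the NC cultures or from crest cells formed in the CP cultures. The first is argued against as the whole source: of 22 genes present in NC and silent in NE and NNE, 9 reached in CP a share of their NC level over 10 times smaller than that of SOX10 (13.7%). The second stays open: 0 of 5 crest list genes among the 22, SOX10 aside, had a share over 3 times smaller than that of SOX10, and they reached 16.7 to 38.3% of their NC level (median 33.7%). Expression of these genes by placode cells themselves was not tested, and the SIX1 reporter gate would remove crest cells without SIX1.

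Some genes were present (at least 5 CPM in every library) in 1 lineage and at most at 5% of that in all others, or silent in it by the same limits. With all libraries used, 9 genes were present in NC alone, each under 1 CPM in hESC, and 10 were silent in NC alone, each over 5 CPM in hESC. In NE the counts were 24 and 16, in CP 1 and 0, and in NNE 10 and 3. Among them CRYZ, TXNRD2 and TYW3, chosen after their values were seen, were at 0.0672 ± 0.0218, 0.195 ± 0.0359 and 0.0749 ± 0.0263 CPM in NC against 24.6, 14.7 and 28.2 in hESC. A property of the NC reporter line or its clone, such as an epigenetic state set before differentiation, is a candidate explanation, since genes present in NC alone kept a median ratio of 0.912 in NC library 2 where crest list genes had 0.429. Crest identity cannot be told apart from it, since the difference of 0.482 between these ratios rests on 1 library. Pseudogene copies of CHCHD2 were silent in NC too, and whether reads were shared among them was not tested. In NE, 15 of the 24 genes present alone were under 1 CPM in hESC. Of the 16 silent there alone, 8 were at 5 CPM or more in hESC. A property of the cells used, apart from lineage, was not tested for NE, CP or NNE.

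In 100 regroupings of the 11 lineage libraries, the real one included, 1 gave as many called genes for NE (8963, highest other 7014), 1 for NC (3350, highest other 699) and 1 for NNE (13131, highest other 3159), and 8, 7 and 7 regroupings called any gene. The counts of specific genes were reached by 1 for NE (1010, highest other 599) and 1 for NC (232, highest other 0). That of NNE was reached by 1 (2126, highest other 273). Each of these 6 counts was thus reached by the real grouping alone. Regroupings put libraries of different lineages in the same group, which widens the spread within groups. Low counts are thus largely built into them, so they do not exclude chance as the source of these counts. They also do not test how large or how stable the counts are. For the number of called lists, 1 regrouping, the real one, reached the 14 of NE (highest other 13). This rests on 1 list, since the NE count was 13 with the replicate block and with 6 of 11 libraries left out in turn, and 5 regroupings reached 13. Of the same regroupings 47 reached the 8 of NC (highest other 13) and 26 the 11 of NNE (highest other 14). Regrouped libraries still hold unequal mixes of the lineages, so lists of correlated genes may be called through lineage differences. The number of called lists therefore does not decide on chance, nor on any single list. For CP, with 2 libraries, 1 regrouping reached the 6704 called genes (highest other 2241) and 1 the 835 specific genes (highest other 0). Its 8 called lists were reached by 58 (highest other 14). The same limits hold for these counts. For each pair of lineages of 3 libraries, 10 splits are too few for a share under 0.05: the real split, 1 of 10, called 6417 genes between NE and NC, 11972 between NE and NNE and 10262 between NC and NNE, and the highest other called 0.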
